A study of Mus musculus with 6 samples.

How the data were processed

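RNA from the stomach of mouse embryos at E13.5 was measured on 6 Affymetrix arrays, 3 of wild type stomach and 3 of stomach from embryos that carry Nkx3.2Cre and R26-SmoM2 (called SmoM2 here). Groups and replicate numbers came from the sample titles and genotype labels. The labels' protocols state Trizol extraction of total RNA and biotin labelling. They do not state that replicates were separate embryos, litters or pools, so the p-values measure the spread between these samples, part of which may be technical. Xist was at 7.11 in wild type 1 and at 11.94 and 11.68 in wild type 2 and 3, so these 3 do not all hold the same embryos.

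The deposited values are log2 signals for 35556 probe sets. RMA (background correction, quantile normalization and probe summary) and affy are named in the submitters' processing notes, and their versions are not given in the sources used here. RMA pulls the arrays towards a common distribution, so a change in the total RNA of a sample would not show, and it compresses small signals. Values ran from 3.79 to 14.72 and the array medians from 8.56 to 8.62. Olfactory and vomeronasal receptor genes, taken as genes that the stomach does not express, had array medians from 6.16 to 6.40, which marks the level of dim probe sets. No detection call was used, and the number of arrays limits the precision of each value.

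Gene names came from the platform annotation of the probe sets. It listed 23410 of them, of which 21789 had 1 gene symbol and 1621 had several. The 12146 others are unnamed here. Symbols were checked through gene identifiers against a table of RefSeq genes on assembly GRCm38.p6, which held 21698 of the 21789, and 0 symbols changed. That table was used only for names and for which genes neighbour each other. Each of the 19938 genes was represented by the probe set with the highest mean over all 6 arrays. Of the changed genes, 9 had more than 1 probe set, and in 0 of these did a probe set have the opposite sign. The 13767 probe sets without exactly 1 symbol stayed out of the comparison.

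SmoM2 was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the log2 values, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p 0.05. A change is given as the log2 difference of the means (SmoM2 minus wild type) with its moderated standard error (SE), and as a fold. Levels are means ± SD over 3 arrays. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the 31 lists tested, and again with the correlation estimated from the data. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. The median change of each list was set against 10000 random lists of the same size matched on mean signal in 20 bins. These draw genes independently and make no allowance for correlation between the members of a list.

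The lists covered hedgehog targets, hedgehog ligands, receptors and transducers, regional regulators of the stomach mesenchyme, smooth muscle, interstitial cells of Cajal, subepithelial mesenchyme, mesothelium, enteric neurons and glia, general epithelium, glandular and stratified stomach epithelium, and intestinal epithelium. Others covered pancreas, liver, erythroid cells, endothelium, leukocytes, cartilage and sclerotome, skeletal muscle, mitosis, DNA replication, YAP and TAZ targets, Wnt targets, Wnt ligands and inhibitors, BMP, FGF and Notch signalling, retinoic acid, fibrous extracellular matrix, immediate early response, and hypoxia and glycolysis. Sex-linked genes (Xist, Eif2s3y, Kdm5d and Uty) were read per array and not tested as a list. Lists share members. Krt8 and Krt18, for example, stand in both the mesothelium and the general epithelium list.

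The genes named in the text followed a rule. It took Smo, Nkx3-2, Gli1, Ptch1 and Hhip, and 1 more gene that is not reported here. It took the 10 largest increases and the 10 largest decreases among genes past the threshold whose groups did not overlap, without predicted genes. Of each list it took up to 4 members past the threshold with the largest change, or, where fewer than 2 passed, the 2 members with the largest change, as values. The groups, the tests, the lists, this rule and 14 kinds of alternative were fixed before the data were examined. Genes named outside the rule, among them Foxf1, Saa1, Wt1 and Krt7, were chosen after their values were seen.

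The alternatives fixed in this way were the replicate number as a block, leaving out each array, filters on dim probe sets at the median and at the 75th percentile of all probe sets, the mean or the most variable of a gene's probe sets, each probe set as its own row, repeated quantile normalization, and centring on the median or on the 75th percentile. They also included an intensity trend in eBayes, robust eBayes, array weights, a linear model without variance moderation, and the estimated correlation for the lists. Chosen after seeing the data were a term for the 2 sets of arrays that correlated best, the olfactory receptor median or the Y-linked signal (mean of Eif2s3y, Kdm5d and Uty) as a covariate, and wild type 3 alone against SmoM2.

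The scripts were tested on simulated data with the mean signals of these arrays. Their spreads were shuffled between genes, and each gene was drawn independently of the others. With 200 of 19938 genes changed in each of 5 draws, limma recovered 34.4% of 1.3-fold, 67.6% of 1.5-fold, 96.4% of 2-fold and 100% of 3-fold changes between SmoM2 and wild type, and 4.37% of its calls were false. Camera found a list of smooth muscle genes shifted by 0.30 log2 in 20 of 20 draws, with 1 call of another list in all draws. In the real data genes of a list correlate (estimated at 0.23 for general epithelium and 0.67 for skeletal muscle). These rates of false calls therefore need not hold for the real arrays. Figures were drawn with matplotlib.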

Results

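Hedgehog proteins are secreted by the gut epithelium and act on the mesenchyme around it. SmoM2 is a form of the transducer Smoothened that is active without ligand, and it was switched on from the Rosa26 locus by a Cre recombinase under the control of Nkx3-2, a gene of the stomach mesenchyme. The comparison asked how gene expression in the embryonic stomach at E13.5 (the embryonic day) changed when the pathway was activated there. It rested on log2 signals of 19938 genes from 3 wild type and 3 SmoM2 arrays of the tissue. Each array measured all cell types of the tissue together.

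Hhip and Ptch1, whose transcripts report hedgehog activity, were higher in the stomachs labelled SmoM2. Hhip, a membrane protein that binds hedgehog ligands and is induced by them, rose 2.43-fold, from 10.42 ± 0.07 to 11.70 ± 0.03 (log2 signal, SD, n = 3; probe set 10579894; limma adjusted p = 0.000175). Ptch1, the hedgehog receptor and itself a target, rose 1.40-fold (log2 change 0.48, SE 0.07, adjusted p = 0.0174). Gli1, a transcription factor induced by the pathway, stood at 10.05 ± 0.13 and 10.47 ± 0.12 (adjusted p = 0.0727), and Smo itself at 11.69 ± 0.03 and 12.04 ± 0.19 (adjusted p = 0.154). Both had every SmoM2 array above every wild type array and did not pass the threshold. Nkx3-2, whose promoter drives the Cre, had a log2 change of -0.12 (SE 0.07, adjusted p = 0.648). Without wild type 1, wild type 2 or SmoM2 3, Ptch1 had an adjusted p of 0.102, 0.0745 and 0.0749.

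**Figure D1:**
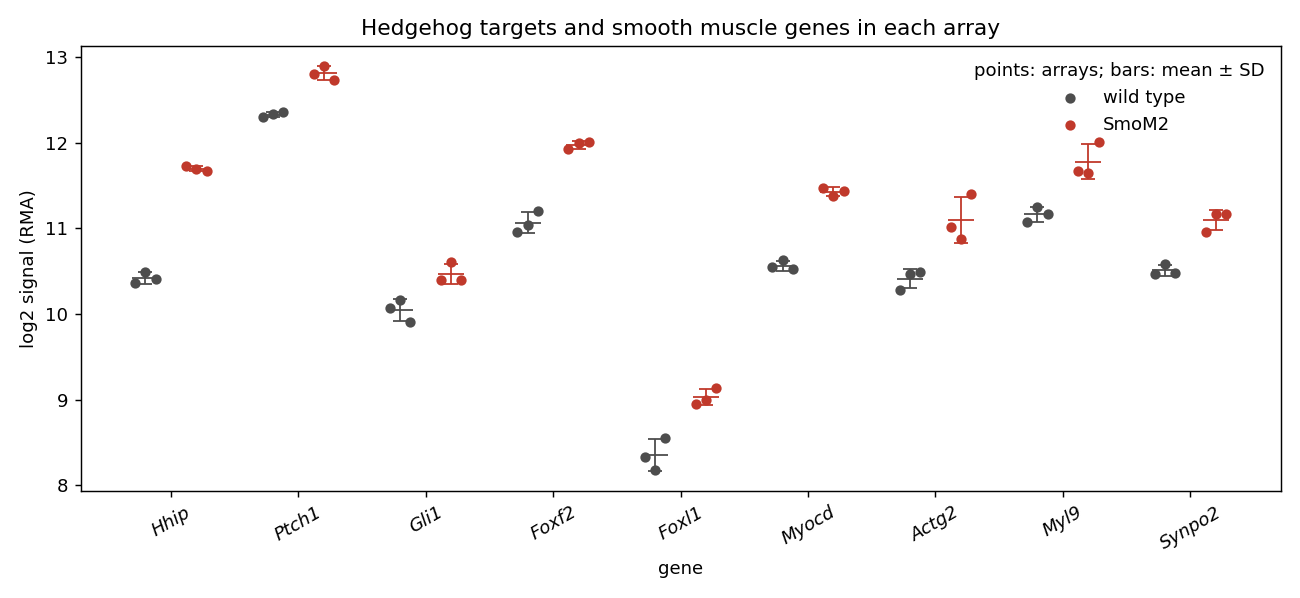
Log2 signal (RMA, vertical axis) of hedgehog targets and smooth muscle genes (horizontal axis) in each of the 3 wild type and 3 SmoM2 arrays, with the mean and SD as bars. For Hhip the means are 10.42 and 11.70, and for every gene shown the 3 SmoM2 arrays lie above the 3 wild type arrays.

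In all, 196 of the 19938 genes changed (0.983%), 65 of them higher and 131 lower in SmoM2. The changes were small. Higher genes rose by 0.35 to 3.47 and lower genes fell by 0.36 to 1.35 on the log2 scale, and 12 genes changed at least 2-fold, 5 up and 7 down. In each of the 196 genes the 3 SmoM2 values lay on one side of the 3 wild type values. Over all genes this held for 3136 (15.7%), where chance gives 10% for 3 against 3. At an unadjusted p under 0.05 there were 2098 genes. Leaving out wild type 1, wild type 2, SmoM2 1 or SmoM2 3 left 51, 62, 80 and 32 genes, with 24, 22, 38 and 13 of them higher and 27, 40, 42 and 19 lower, while leaving out wild type 3 or SmoM2 2 gave 228 and 247, with 56 and 63 higher and 172 and 184 lower. The count at 2-fold or more was 7 without wild type 1 and 23 without wild type 3. Without variance moderation 0 genes passed, with 1873 at an unadjusted p under 0.05.

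The largest increases were in genes of varied function. AI506816, annotated as a long noncoding RNA, rose 11.1-fold, from 6.73, 8.72 and 8.24 in the wild type arrays to 11.21, 11.44 and 11.45 in SmoM2 (adjusted p = 0.00584). Its probe set (10351504) is numbered among probe sets of a chromosome other than that of AI506816, so the locus it reports is uncertain. Tdo2, which degrades tryptophan, rose 2.42-fold, Epyc, a small proteoglycan of cartilage, 2.14-fold, and Saa2, an acute phase protein, 2.02-fold. Saa2 is close in sequence to Saa1, which also rose, so their signals may not be separate. Lum, a small proteoglycan that binds collagen, rose 1.89-fold, and Csn3, best known as a milk casein, 1.91-fold. Foxf2, a forkhead factor of the gut mesenchyme, rose 1.88-fold, Myocd, the coactivator of smooth muscle genes, 1.82-fold, and Phlda2, an imprinted gene that limits placental growth, 1.79-fold. Adjusted p ranged from 0.000175 for Hhip to 0.0121 for Lum over these 10 genes.

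The largest decreases were also in genes of varied function, with Dcx and Nefm the 2 of 10 on the list of enteric neurons and glia. Ndnf, a secreted neurotrophic factor, was 2.55-fold lower in SmoM2 (log2 change -1.35, SE 0.10, adjusted p = 0.000696). Epha3, an ephrin receptor, was 2.14-fold lower, Dcx, a microtubule protein of young neurons, 2.11-fold, Zim1, an imprinted zinc finger gene, 2.05-fold, and Gabrb1, a GABA receptor subunit, 2.03-fold. Slc40a1, the iron exporter ferroportin, and Nefm, a neurofilament subunit, were both 2.01-fold lower. Bves, a cell adhesion gene first found in heart muscle and epicardium, was 1.98-fold lower, Cpa1, a pancreatic digestive enzyme, 1.98-fold, and Capn6, a calpain family member, 1.92-fold. The largest adjusted p among these 10 was 0.0258, for Cpa1.

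Of the 196 genes, 30 (13 higher and 17 lower) passed in each of the 6 fits that left out 1 array. Among the named genes these were Hhip, Tdo2, Epyc, Saa2, Csn3, Foxf2, Myocd, Phlda2, Ndnf, Epha3, Gabrb1, Slc40a1, Nefm and Capn6, and from the lists below Tlx1, Dbh, Cym, Hey2 and Rxrg. AI506816, Lum, Dcx, Zim1, Dsp and Igfbp5 lost the call only without SmoM2 3, at an adjusted p of 0.0504, 0.0774, 0.0562, 0.0655, 0.0774 and 0.0504, and Bves only without wild type 1 (adjusted p = 0.0559). The other changed genes that the rule named lost it without 2 or more of the arrays. The sign of each of the 196 changes was the same in each of these fits. It could not differ, since the groups of these genes did not overlap.

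Hedgehog targets shifted upward as a list (camera adjusted p = 6.36e-05; adjusted p = 0.169 with an estimated correlation). Of 19 measured members 5 rose, 1 fell and 13 did not pass, with 7 and 1 past the threshold when adjusted over the list alone. Besides Hhip, Foxf2 and Ptch1, the forkhead gene Foxl1 of the mesenchyme under the epithelium rose 1.60-fold (adjusted p = 0.0188) and its neighbour Foxf1 also rose. Igf1, a growth factor, was the member that fell (log2 change -0.53, SE 0.09, adjusted p = 0.0245). The list of ligands, receptors and transducers shifted downward (adjusted p = 0.00337; adjusted p = 0.322 with an estimated correlation). In it 0 of 20 rose and 1 fell, the coreceptor Boc (log2 change -0.55, SE 0.09, adjusted p = 0.0225), with 1 higher and 4 lower when adjusted over the list alone. This shift did not pass with the Y-linked signal as a covariate (adjusted p = 0.174, median -0.04) or with wild type 3 alone against SmoM2 (adjusted p = 0.278, median -0.02), both chosen after seeing the data. Among probe sets above the 75th percentile it did not pass either (adjusted p = 0.229), with 6 members left and a larger median (-0.15 against -0.08). Shh, the epithelial ligand, stood at 10.68 ± 0.11 in wild type and 10.25 ± 0.10 in SmoM2 (adjusted p = 0.0532).

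The smooth muscle list shifted upward. Of 33 measured members 7 rose, 1 fell and 25 did not pass, with 15 and 2 when adjusted over the list alone, and 28 had a positive change (camera adjusted p = 9.97e-12; adjusted p = 0.169 with an estimated correlation). The risers with the largest changes were Myocd, the enteric smooth muscle actin Actg2 (1.61-fold, adjusted p = 0.0405), the myosin light chain Myl9 (1.53-fold, adjusted p = 0.0286) and Synpo2, an actin-binding protein (log2 change 0.59, adjusted p = 0.0142). Des, the muscle intermediate filament desmin, was the 1 member that fell (log2 change -0.54, adjusted p = 0.0263; named after its value was seen). The median of the list was 0.15 above wild type on the log2 scale and above that of 100% of the random lists, which make no allowance for correlated members.

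Other mesenchymal groups were mixed. Subepithelial mesenchyme shifted upward (adjusted p = 0.00855; adjusted p = 0.372 with an estimated correlation), with 3 of 18 members higher, 1 lower and 14 not past the threshold (6 and 2 adjusted over the list alone). Foxl1, the growth factor Nrg1 (1.36-fold) and the BMP ligand Bmp5 (1.35-fold) rose, and the transcription factor Sox6 was 1.32-fold lower. The shift, with a median of 0.10, did not pass without wild type 3 (adjusted p = 0.0992, median 0.10), without SmoM2 2 (adjusted p = 0.172, median 0.11) or among probe sets above the 75th percentile (adjusted p = 0.0851, 9 members left, median 0.02). Of 28 regional regulators of the stomach mesenchyme, 4 rose and 1 fell (5 and 4 adjusted over the list alone), and the list did not shift (adjusted p = 0.458). Foxf2, Foxl1, Foxf1 and Foxd1 rose. Tlx1, a homeobox gene needed to form the spleen, fell 1.92-fold (9.28 ± 0.05 to 8.33 ± 0.11, n = 3, adjusted p = 0.00135).

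Part of the epithelial transcripts were lower in SmoM2. In the general epithelium list 11 of 29 members fell, 0 rose and 18 did not pass (19 lower adjusted over the list alone), with a median log2 change of -0.33 and 25 negative changes (camera adjusted p = 1.84e-16; adjusted p = 0.169 with an estimated correlation). Esrp1, an epithelial splicing factor, fell 1.60-fold, the tight junction protein Cldn6 1.58-fold, Cdh1, which encodes E-cadherin, 1.49-fold and the keratin Krt18 1.48-fold, with adjusted p between 0.0111 and 0.0245. In the glandular stomach list 2 of 32 fell, 0 rose and 30 did not pass (11 lower adjusted over the list alone), and 16 had a positive change. These were Cym, the milk-clotting protease chymosin (1.75-fold lower, adjusted p = 0.00373), and the endodermal factor Gata6 (1.49-fold lower, adjusted p = 0.0241). That list shifted downward (adjusted p = 0.00541; adjusted p = 0.724 with an estimated correlation), but not without wild type 3 (adjusted p = 0.123) or SmoM2 2 (adjusted p = 0.296), and its median, -0.02, turned to 0.02 and 0.05 in these and to 0.02 without wild type 1 or with centring on the 75th percentile. Over all 19 alternatives the median of the glandular list ran from -0.33 to 0.05, and camera gave a downward direction in 19 of them. In the forestomach list 1 of 22 fell, the desmosomal protein Dsp (1.59-fold lower, adjusted p = 0.0111; 3 lower adjusted over the list alone), 15 had a positive change, and the list did not shift (adjusted p = 0.645). Jup, another desmosomal protein, was at 11.40 ± 0.07 and 11.02 ± 0.12 (adjusted p = 0.0784).

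**Figure D2:**
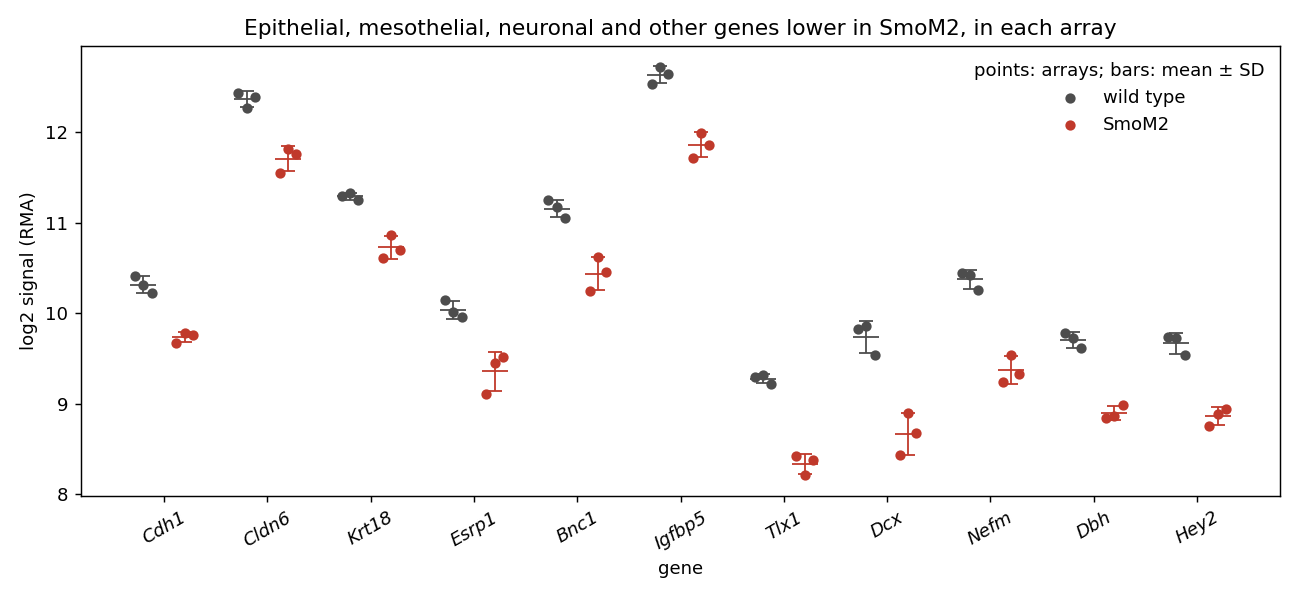
Log2 signal (RMA, vertical axis) of epithelial, mesothelial, neuronal and other genes (horizontal axis) that fell, in each of the 3 wild type and 3 SmoM2 arrays, with the mean and SD as bars. For Tlx1 the means are 9.28 and 8.33, and for every gene shown the 3 SmoM2 arrays lie below the 3 wild type arrays.

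Part of the mesothelial and neuronal transcripts were lower too. In the mesothelium list 6 of 19 members fell, 0 rose and 13 did not pass (10 lower adjusted over the list alone; camera adjusted p = 6.42e-11; adjusted p = 0.169 with an estimated correlation). Igfbp5, an insulin-like growth factor binding protein, was 1.71-fold lower and Bnc1, a zinc finger factor of mesothelium and stratified epithelia, 1.65-fold. The others were Wt1 and the keratins Krt7, Krt8 and Krt18, which epithelium also makes. Of 27 genes of enteric neurons and glia 5 fell, 0 rose and 22 did not pass (8 lower and 1 higher adjusted over the list alone; 8 positive changes; camera adjusted p = 6.36e-05; adjusted p = 0.475 with an estimated correlation). Among probe sets above the 75th percentile that shift did not pass (adjusted p = 0.679, 8 members left, median -0.03). Dcx, Nefm, the neurofilament subunit Nefl (1.79-fold lower) and Dbh, which makes noradrenaline (1.75-fold lower), had the largest changes.

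Markers of blood and vessels were lower as lists, with 0 members past the threshold in limma over all genes. Erythroid genes (21 measured, 2 lower adjusted over the list alone) had an adjusted p of 0.000129 in camera, with Hbb-bh1 at a log2 change of -0.38 and Alas2 at -0.37. The same list had an adjusted p = 0.372 with an estimated correlation. Leukocyte genes (26 measured, 1 lower adjusted over the list alone) had an adjusted p of 6.32e-06, with Pf4 at -0.48 and Lyz2 at -0.39, and an adjusted p = 0.253 with an estimated correlation. Endothelial genes (30 measured, 2 lower adjusted over the list alone) had an adjusted p of 0.00175, with Kdr at -0.36 and Stab1 at -0.34, and an adjusted p = 0.521 with an estimated correlation. The endothelial shift, with a median of -0.06, did not pass without SmoM2 1 (adjusted p = 0.103, median -0.05) or with the Y-linked signal as a covariate (adjusted p = 0.108, median -0.06). Skeletal muscle genes shifted upward (29 measured, 0 past the threshold and 1 higher adjusted over the list alone; adjusted p = 0.000695; adjusted p = 0.773 with an estimated correlation), with Acta1 at a log2 change of 0.41 and Actc1 at 0.28. This shift did not pass without SmoM2 1 (adjusted p = 0.288, median 0.01 against 0.08), with a term for 2 sets of arrays described below (adjusted p = 0.0684, median 0.02), with the Y-linked signal as a covariate (adjusted p = 0.987) or with wild type 3 alone against SmoM2 (adjusted p = 0.737), and in the last 2 the median of the list turned to -0.03.

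Among signalling and matrix lists, 2 of 21 Notch genes fell, 0 rose and 19 did not pass (8 lower adjusted over the list alone; camera adjusted p = 0.000135; adjusted p = 0.169 with an estimated correlation). They were Hey2, a Notch target (1.75-fold lower, adjusted p = 0.00373), and the coactivator Maml2 (1.52-fold lower, adjusted p = 0.0365). Fibrous extracellular matrix shifted downward (adjusted p = 0.00074; adjusted p = 0.333 with an estimated correlation), with 2 of 34 members higher, 1 lower and 31 not past the threshold (2 and 9 adjusted over the list alone). The risers were the small proteoglycans Lum and Ogn (1.62-fold), against the direction of the list, and the collagen gene Col1a2 fell 1.36-fold. That shift, with a median of -0.10, did not pass without wild type 2 (adjusted p = 0.0694, median -0.08) or with wild type 3 alone against SmoM2 (adjusted p = 0.278, median -0.08). Hypoxia and glycolysis genes shifted upward (adjusted p = 0.000162; adjusted p = 0.169 with an estimated correlation), with 1 of 24 higher, the mitophagy gene Bnip3 (1.37-fold), whose probe set is likewise numbered among those of another chromosome, and 1 lower, the glucose transporter Slc2a3 (1.41-fold lower; 4 and 1 adjusted over the list alone).

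**Figure D3:**
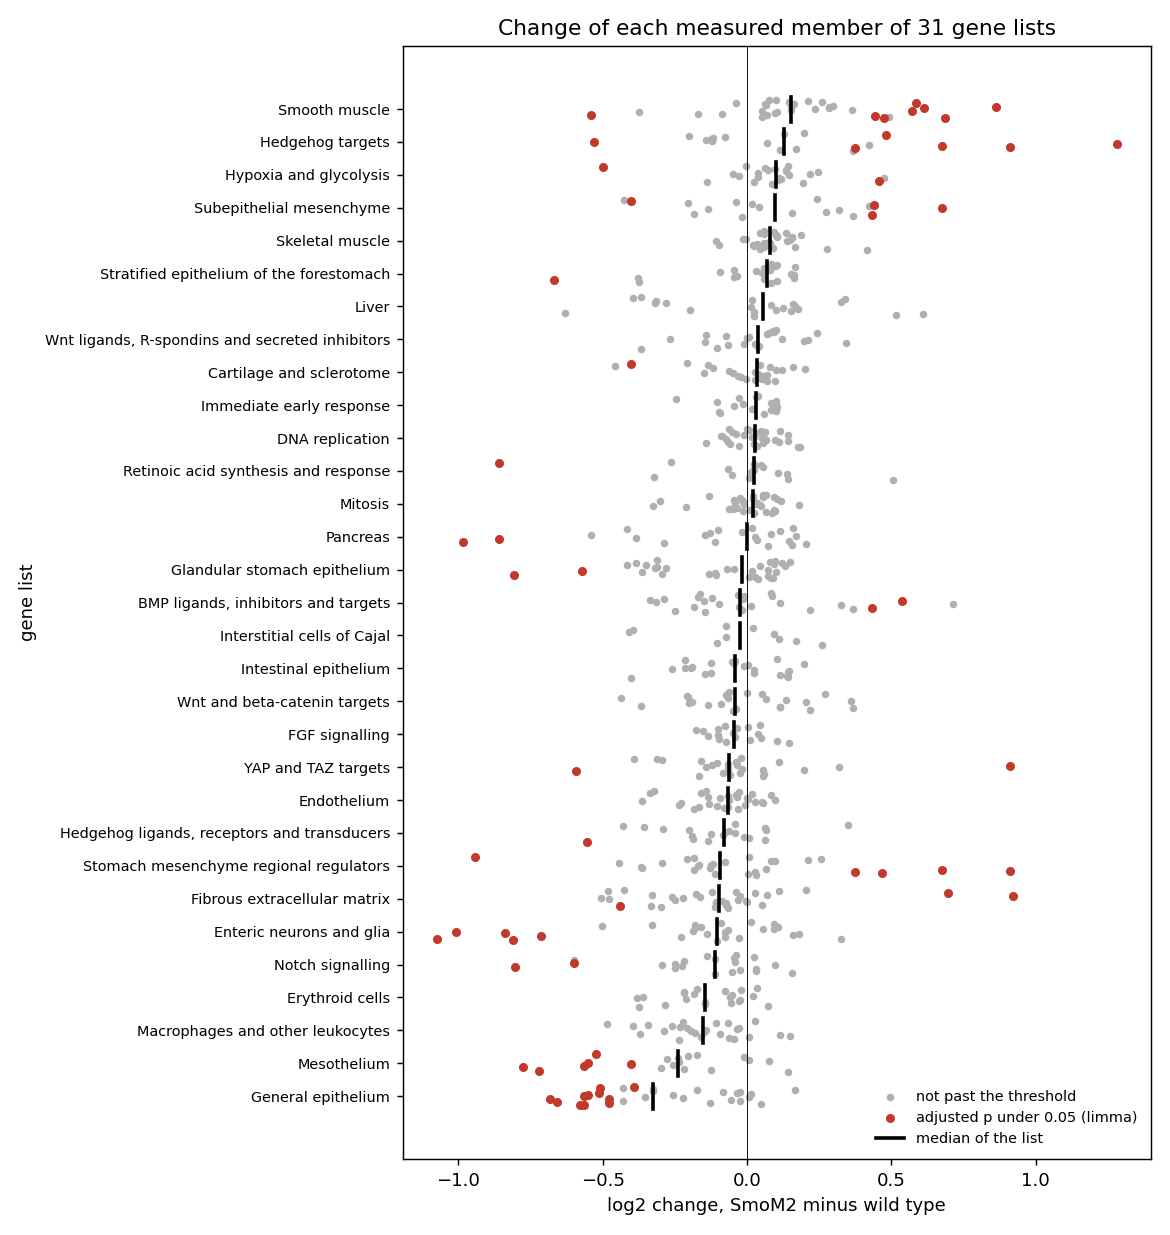
Log2 change (SmoM2 minus wild type, horizontal axis) of each measured member of the 31 gene lists tested (vertical axis), with members past adjusted p 0.05 in limma in red and the median of each list as a black bar. The general epithelium list has the lowest median (-0.33) and the smooth muscle list the highest (0.15).

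The other lists did not shift, with camera adjusted p from 0.206 for pancreas to 0.990 for Wnt targets. In the pancreas list 2 of 22 fell, Cpa1 and the hormone gene Gcg (1.81-fold lower). BMP signalling had 2 of 26 members higher, Bmp5 and the BMP inhibitor Grem1 (1.45-fold). Of 26 YAP and TAZ targets 1 rose, Foxf2, and 1 fell, Ccdc80 (1.51-fold lower). In the retinoic acid list 1 of 16 fell, the receptor gene Rxrg (1.81-fold lower, adjusted p = 0.00401), while Aldh1a1 had a log2 change of 0.51 (adjusted p = 0.289). In the list of cartilage and sclerotome 1 of 26 fell, Sox6, and Ptprd was at -0.46 (adjusted p = 0.104). No member passed in the lists of interstitial cells of Cajal (Kit -0.41, Kitl -0.39), intestinal epithelium (Anpep -0.40, Hnf4g -0.26), liver (Ambp -0.63, Alb 0.61), mitosis (Cenpf -0.32, Mki67 -0.30) and DNA replication (Ccne2 0.18, Ccne1 0.18). The same held for Wnt targets (Prox1 -0.44, Bmp4 0.37), Wnt ligands and inhibitors (Dkk1 -0.37, Rspo3 0.34), FGF signalling (Il17rd -0.18, Fgfr4 -0.15) and immediate early genes (Klf4 -0.25, Jun -0.10). Adjusted over the list alone, BMP signalling had 5 members higher and 4 lower, Wnt targets 3 and 2, YAP and TAZ targets 2 and 3, and pancreas 0 and 4, and the lists of cartilage, retinoic acid, interstitial cells, intestinal epithelium, liver, mitosis, DNA replication, Wnt ligands, FGF and immediate early genes at most 2 in a direction. Some of these lists passed under an alternative. DNA replication passed as higher in 8 of 19, among them without SmoM2 1 (adjusted p = 0.0123) and without SmoM2 3 (adjusted p = 0.0373), and pancreas as lower in 5 of 19, among them without wild type 2 (adjusted p = 0.00598), without SmoM2 1 (adjusted p = 0.0188) and with the replicate block (adjusted p = 0.0340), while 1 of the 5, the 75th percentile filter, left it 2 members. Liver passed in 3, as higher without SmoM2 1 (adjusted p = 0.0430) and as lower with the Y-linked signal as a covariate (adjusted p = 0.0389) and with wild type 3 alone against SmoM2 (adjusted p = 7.83e-05). Intestinal epithelium and cartilage passed as lower and mitosis as higher with these last 2 choices, intestinal epithelium also with the term for the 2 sets of arrays (adjusted p = 0.0387), and Wnt targets and Wnt ligands as higher among probe sets above the 75th percentile (adjusted p of 0.0147 and 0.00156), where they had 6 and 5 members left. Cartilage and stratified epithelium, with 2 and 1 members left there, are too few to be read as lists. Against the random lists, the medians of the 5 lists that shifted upward lay above 99.8% to 100% of them, and those of the 10 that shifted downward above 0% to 2.52%, except glandular stomach (12.4%) and endothelium (6.01%). Some lists that camera did not call lay as far out, namely regional regulators (0.07%), intestinal epithelium (0.53%), stratified epithelium (97.8%), liver (98.0%) and DNA replication (99.1%). Mean, median and test differed in sign in the lists of stratified epithelium, pancreas, liver, cartilage, mitosis, Wnt targets, BMP signalling and retinoic acid. In total 15 of 31 lists shifted, 5 upward and 10 downward, and 0 did so with an estimated correlation, where the smallest adjusted p was 0.169. Splits of the arrays that mix the genotypes, described below, also gave 5 to 13 lists each. None of them balances the genotypes, so part of the genotype difference remains in each and these lists need not arise without it.

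The arrays also differed in ways the genotypes do not set. Xist was at 7.11 in wild type 1 and between 11.43 and 12.37 in the other arrays. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty was 10.37, 9.92 and 9.07 in wild type 1 to 3 and 8.71, 8.94 and 9.27 in SmoM2 1 to 3, so wild type 1 and 2 held the most Y-linked signal and wild type 3 lay within the SmoM2 range. Wild type 2 held high Xist (11.94) together with high Y-linked signal, so it may hold embryos of both sexes. With that signal as a covariate, added after seeing the data, 22 genes passed, 14 higher and 8 lower, and 19 of them were among the 196, all of which kept their sign at a median of 0.914 of their size while their median SE went from 0.08 to 0.12. With wild type 3 alone against SmoM2, also chosen after seeing the data, 8 genes passed, while the 196 kept their sign at a median of 0.926 of their size and their median SE went to 0.13. Alb, the serum albumin made by the liver, ran from 10.31 to 12.58 with no order by genotype. Over all probe sets, wild type 1, wild type 2 and SmoM2 2 correlated best with each other, and so did the other 3 arrays. With a term for these 2 sets, a further choice made after seeing the data, 324 genes passed, among them all 196.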

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

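Of the 91 genes the rule named, 54 had changed, and each kept its sign under every alternative that gave it a value, with 951 of 1213 such values past the threshold and 262 not. The 196 changed genes, where measured, also kept their sign under each alternative. As their groups did not overlap, leaving out arrays, the replicate block, array weights or another variance estimate could not turn a sign. The kept signs therefore lend no support in those fits. The count of genes moved between alternatives. Leaving out 1 array gave 32 to 247 genes (13 to 63 higher, 19 to 184 lower), 7 to 23 at 2-fold or more, and 13 to 16 lists. The adjusted p then ran from 1.05e-05 to 0.00674 for hedgehog targets and from 1.80e-14 to 8.12e-08 for smooth muscle. The count was 51 without wild type 1, 62 without wild type 2, 80 without SmoM2 1 and 32 without SmoM2 3, but 228 without wild type 3 and 247 without SmoM2 2, so sample number alone does not account for the falls. The count at 2-fold or more was 7 without wild type 1 and 23 without wild type 3. With the replicate block 698 genes passed (158 higher, 540 lower), 196 of the 196 among them. The labels do not state that the numbers pair the samples. Deviations of same-numbered arrays correlated at -0.10, 0.52 and 0.06, which does not settle whether they do. Of the list calls the block changed that of pancreas alone. An intensity trend gave 336 genes (101 higher, 235 lower), and no variance moderation gave 0 (0 higher, 0 lower, 0 at 2-fold), with 1873 at an unadjusted p under 0.05. Array weights, whose estimation stopped before it converged, gave 4110 (1689 higher, 2421 lower, 41 at 2-fold) with weights from 0.327 to 6.02. Centring on the 75th percentile gave 120 (43 higher, 77 lower), a filter at the median 203 lower genes among fewer tested, and one at the 75th percentile 3 genes at 2-fold. With an estimated correlation 0 lists passed, at 0.169 for both hedgehog targets and smooth muscle. Under the 75th percentile filter the lists of intestinal epithelium, leukocytes and skeletal muscle had no member left. Of the choices made after seeing the data, the term for the 2 sets of arrays gave 324 genes (227 lower), the olfactory receptor covariate 729 (173 higher, 556 lower), the Y-linked covariate 22 (14 higher, 8 lower, 6 at 2-fold), and wild type 3 alone, taken to vary like SmoM2, 8 (6 higher, 2 lower, 5 at 2-fold), with the 196 changes at a median of 0.914 and 0.926 of their size in the last 2. Why counts moved was not tested, except for the Y-linked covariate. Scaling moved the median of all genes by at most 0.04. Dim probe sets near the receptor level of 6.16 to 6.40 limit what can be seen, as their changes are compressed.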

Other observations

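Among the 196 changed genes were others outside the lists, named here after their values were seen. Sema3a, a repellent of growing axons, rose 1.64-fold (limma adjusted p = 0.00287), Gdnf, which guides enteric neural crest cells, 1.41-fold (adjusted p = 0.0247) and Sostdc1, an inhibitor of BMP and Wnt signals, 1.61-fold (adjusted p = 0.00427). Slit2, another axon repellent, fell 1.66-fold (adjusted p = 0.0241), and its receptor Robo2 fell 1.38-fold (adjusted p = 0.0241). The cytokine Il33 rose 1.66-fold (adjusted p = 0.0225) and the prostaglandin synthase Ptgs2 1.43-fold (adjusted p = 0.0301). The vasopressin receptor Avpr1a (1.71-fold) and the muscarinic receptor Chrm2 (1.46-fold), both of which act in smooth muscle, also rose, with adjusted p of 0.0181 and 0.0227. Each change had 3 of 3 SmoM2 arrays on one side of all wild type arrays, as did all 196, so this adds no support for these genes.

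Lhx9, a LIM homeobox gene of developing mesenchyme and gonad, fell 1.63-fold (adjusted p = 0.00373), as did Tlx1 and Wt1, which are both needed for the spleen to form. Of the 13767 probe sets without exactly 1 gene symbol, fitted on their own, limma called 0, with 771 at an unadjusted p under 0.05 and a smallest adjusted p of 0.800.

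The tests of imprinted genes, potassium channels, epithelium share, the parts of the Y-linked fit, the chromosome segment with its windows of neighbouring genes, the numbering of probe sets and the distance of AI506816, the count of calls kept with a term for the 2 sets of arrays, and the splits for changed, higher and lower genes were chosen after the result was seen. With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The splits other than the real one do not balance the genotypes, so each still carries part of the genotype difference. Their counts therefore do not show what arises without genotype. The real split gave 196 genes, 131 of them lower, and the highest other split gave 81 and 77, so 1 of 10 splits gave as many. For higher genes 2 of 10 splits gave as many (65 against 77 in one direction), and for changes of 2-fold or more also 2 (12 against 12). The other split with such counts set wild type 1, wild type 2 and SmoM2 2 against the rest and points to a structure of the samples that crosses genotype. For lists the real split gave 15 and the highest other 13 (1 of 10). For hedgehog targets the camera p was 1.05e-05 against 0.0311, and for smooth muscle 6.43e-13 against 4.82e-07 (1 of 10 each).

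Whether the calls follow genotype or another difference between the arrays was weighed for sex and for the 2 sets of arrays. If Y-linked content caused the calls, wild type 3, whose Y-linked signal is nearest to SmoM2, should lie near SmoM2 in the 228 genes called without it. Its median position was 0.774, on a scale from 0 at the SmoM2 mean to 1 at the mean of wild type 1 and 2, with a lower quartile of 0.573, which argues against sex as the whole cause. With the Y-linked covariate the 196 changes kept their sign at a median of 0.914 of their size, while their median SE went from 0.08 to 0.12. At the p that the 196 genes reached (at most 0.000488), 139 of them passed with the changes of that fit alone, 58 with its SE alone and 52 with both and its degrees of freedom, before adjustment left 19. SmoM2 2 lay at a median of 0.714 between wild type (0) and SmoM2 1 and 3 (1) in 247 genes called without it, short of the 0.75 set beforehand as the value that would speak against the 2 sets, so this test alone leaves them open. Held out in the same way, wild type 1, wild type 2, SmoM2 1 and SmoM2 3 had medians of 1.08, 0.93, 1.02 and 0.97. The medians of wild type 3 and SmoM2 2 were the lowest. Each array was scored on its own set of called genes, 51, 62, 80 and 32 for wild type 1, wild type 2, SmoM2 1 and SmoM2 3. The medians are therefore not directly comparable between arrays. All 196 genes passed with a term for the 2 sets, a check made to decide only after the 0.714 was seen. The 196 genes were called with groups that did not overlap, and a gene set by the 2 sets alone would have overlapping groups. The outcome of this check was thus nearly fixed by the selection and does not decide. A part of single changes may still come from sex or from the 2 sets, and genotype stays a hypothesis for the rest.

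The lower epithelial transcripts may reflect a smaller share of epithelium in the SmoM2 samples. In that case bright transcripts of other stomach epithelium should be lower by a similar amount. The 9 such members of the glandular and forestomach lists outside the general list had a median log2 change of -0.38, all 9 lower, against -0.48 for the 11 bright general members. As bright was set on the wild type mean, which favours decreases, it was also set on the mean of all arrays, and the 5 members then left had a median of -0.36, all 5 lower, against -0.48 for 8 general members. The 44 dimmer members had a median of 0.06, where the 18 dimmer general members had -0.20. Dimmer here means below the 75th percentile of all probe sets (10.11), far above the olfactory receptor level, so compression need not hold for all of them. Among the dimmer general members, Esrp1 (wild type mean 10.04, log2 change -0.68) and Ap1m2 (9.35, -0.56) passed the threshold, and none rose past it. The median of the 44 goes against a smaller share as far as the tissue expresses them. No detection call was used, so how many it expresses is not known and they do not decide. Against a smaller share stand the bright Lsr (0.01), Prom1 (-0.02) and Ctse (-0.11), which did not pass, so the share stays a hypothesis. With a term for the 2 sets of arrays the median of the general list was -0.36 against -0.33 without it, which argues against those sets. Lower transcription within epithelial cells was not tested and stays open.

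The probe set named AI506816 gave the largest change. Wild type 2 and 3, which hold Xist like the SmoM2 arrays, lay at least 2.64 log2 units below the SmoM2 mean. Wild type 2 also held more Y-linked signal (9.92) than the SmoM2 arrays, so only wild type 3 (9.07) matches them in both. These values argue against sex as the whole cause, with wild type 3 alone as the close match. A chromosome segment carried along with the Nkx3-2 Cre allele could change genes near it, and 8 of the 200 tested genes nearest to Nkx3-2 had changed (4%, 7 of them lower, Gabrb1 and Slit2 among them) against 0.951% elsewhere (one-sided Fisher's exact p = 0.000831). That p met the bound set for such a segment, and the checks that follow were added after it was seen. Over the genome, 1.23% of windows of this many neighbouring genes held as many calls. Whether AI506816 belongs to such a segment stays open, since 1 of the 188 tested genes between it and Nkx3-2 had changed and its probe set is numbered between those of Olfml2b, Dusp12, Fcgr4 and Cfap126, which lie on another chromosome. Of 19266 probe sets whose 4 nearest numbered neighbours share a chromosome, 505 (2.62%) were annotated to another.

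Of 45 imprinted genes measured, 6 had changed (13.3% against 0.955% of other genes; one-sided Fisher's exact p = 4.95e-06), with Phlda2 and Nap1l5 higher and Zim1, Peg3, Igf2r and Ddc lower. Of 92 genes with a Kcn symbol, 6 had changed (6.52% against 0.957%; one-sided Fisher's exact p = 0.000296), with Kcnd3, Kcng1, Kcne3 and Kcnmb1 higher and Kcnab1 and Kcnip4 lower. Changed genes lay at most 3 genes apart in 24 pairs, such as Lum and Epyc, Saa1 and Saa2, Foxf1 and Foxl1, and Nefl and Nefm, several of them related in sequence, against a median of 6 in 10000 random draws (permutation p = 0.0001, the smallest they can give). Of the 24, 7 come from 1 run of 6 neighbours that all fell (Capn6, Dcx, Trpc5, Rtl4, Lhfpl1 and Amot), and 3 of the draws had as many pairs as the 17 outside it, a count made after the result was seen. The first 2 of these are hypotheses found and tested on the same arrays, and in all 3 genes are not independent replicates.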
